A study of Mus musculus with 2 samples.

How the data were processed

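Messenger RNA was sequenced from macrophage cultures labelled as RAW 264.7, a mouse macrophage line, on an Illumina HiSeq 2500, per the labels. The series held 2 libraries. The library labelled M2+GANT61 came from cells given GANT61, a small molecule that blocks the GLI transcription factors of Hedgehog signalling. The library labelled M2+DMSO came from cells given the solvent DMSO. Per the labels' protocols, GANT61 was used at 10 µM, and either agent was added 4 h before interleukin 4 (IL-4). Macrophage colony-stimulating factor (M-CSF) was used at 20 ng/mL and IL-4 at 10 ng/mL. The labels' protocols gave the time with IL-4 as 15 min in the treatment text and 24 h in the growth text, and the values below cannot be tied to either. RNA was isolated on columns and made into libraries by a standard Illumina procedure, per the labels' protocols.

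The authors deposited a table of estimated counts of reads per gene, not normalized, and a table of RPKM values, each with 1 column per library. RPKM values are read counts divided by gene model length and library total. The submitters' processing notes named STAR, HISAT2, cutadapt, SAMtools and Partek, and the builds mm10 and hg19. Their roles, order and versions, the read counter, the gene annotation and the strand setting were not given in the sources used here. In the deposited counts, 29.54% of the values of the DMSO-labelled library and 29.26% of those of the GANT61-labelled library were not whole numbers. These expected counts were rounded to whole numbers first. Reads shared by near-identical genes can therefore have been split between copies, and reads of overlapping or antisense genes may not have been told apart. The deposited RPKM values differed from the counts, gene by gene, by a factor of 1.0969 between the libraries. The gene totals differed by 1.0681, so the library total behind the RPKM values was not the sum over the listed genes.

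The columns were tied to the libraries by the treatment in their names. The numbers in the column names did not match the numbers in the sample titles. The expression levels of both libraries included abundant markers of other cell types. For these reasons each library is named by its label throughout.

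The table listed 20003 genes, of which 656 had no reads in either library, and 12 rows had an empty symbol column. The totals were 61632784 reads for the DMSO-labelled library and 57705874 for the GANT61-labelled library, over 18730 and 18376 genes with reads. A count of 0 allowed up to 3 counts, a counts-per-million (CPM) level of 0.0487 and 0.052 of those totals. Rn45s, the precursor of ribosomal RNA, took 0.849% and 0.58% of the reads. The 10 most abundant genes took 4.9% and 4.8%. Mitochondrially encoded genes were not analysed here.

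With 1 library per group there was no replicate check, so no test across conditions was made and no p-value is given. Counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. The ratio of the GANT61-labelled to the DMSO-labelled library was computed from scaled counts with a prior count of 0.5 per library. Each ratio has a 95% exact Clopper-Pearson binomial interval, computed with scipy 1.17.1. The intervals and the limit for a count of 0 cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was called higher or lower by a fixed rule of size. Its ratio had to be at least 1.5, or at most the inverse, with an interval excluding 1 and a mean of at least 1 CPM. This rule compares these libraries, not the conditions. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

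Before the data were examined, 45 gene lists were fixed, with 926 entries and 895 distinct genes. Of these, 18 entries were missing from the table, 15 of them mitochondrially encoded genes, so that list gave no value. For each list with at least 5 measured members, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart where its median lay below the 2.5th or above the 97.5th percentile of these. A further 5 lists were written after the data were seen: adipocytes, milk proteins, erythroid genes, matrix metalloproteinases, and keratins of stratified and wound epithelium.

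The genes named were chosen by a rule fixed before the data were examined. It took 8 Hedgehog readout genes and 8 macrophage and sugar nucleotide genes whatever their values. It took the 10 largest and 10 smallest ratios among called genes with a mean of at least 5 CPM, leaving out predicted gene models and genes with 0 reads in a library. It took up to 4 called members of each list, or up to 2 abundant members where none was called. Some genes that the rule names are not reported here. Lists were described where they stood apart or had at least 3 called members. Cell type markers outside this rule, and the genes Xist, Ptprc and Fos, were chosen after their values were seen. Gene positions are from the GENCODE annotation of mm10, 1-based.

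The rule was tested on simulated data drawn from the real genes' means and library sizes, with 200 genes changed by known folds. With counting error alone, 12 of 13721 unchanged genes were called. With an added spread between replicates, given as a coefficient of variation, 1.09% of unchanged genes were called at 0.1, 16.61% at 0.2 and 34.9% at 0.3. Of 50 genes changed by 1.5-fold, 54% were recovered under counting error alone, because a ratio at the threshold falls on either side of it. At 2-fold the share was 98% under counting error alone and 82% at a coefficient of 0.3.

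The alternatives were total counts, upper-quartile scaling, DESeq2 1.42.0 size factors, no floor and a floor of 5 CPM, fold thresholds of 2 and 3, no interval and a 99% interval, and a prior count of 2. Others used the deposited RPKM values with a pseudocount of 0.1, left out the 10 most abundant genes, thinned the deeper library to 93.63% of its reads, or took the mean of a list in place of the median. After the data were seen, 3 alternatives were added: a trend with gene length removed, a trend with GC content removed, and adipocyte, milk protein and erythroid genes left out.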

Results

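The effect of blocking Hedgehog signalling on the transcriptome of alternatively activated (M2) macrophages was the question of the series. RNA was sequenced from 2 libraries, 1 labelled M2+GANT61 and 1 labelled M2+DMSO. GANT61 inhibits the GLI transcription factors, which act at the end of the Hedgehog pathway. The cells were labelled RAW 264.7, a mouse macrophage line, and had been given M-CSF and IL-4. The libraries held 57705874 and 61632784 reads. With 1 library per group no difference below has a replicate check, and the 95% intervals cover counting error only.

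Both libraries held transcripts that mark cells other than macrophages, some of them abundant. Col3a1, a fibrillar collagen of fibroblasts, was at 3044 CPM in the DMSO-labelled library and 3394 CPM in the GANT61-labelled library. Krt18, a keratin of simple epithelium, was at 945.8 and 551 CPM. Pecam1, an endothelial adhesion molecule, was at 197 and 217 CPM, and Cd3e, a subunit of the T cell receptor complex, at 14.2 and 14.2 CPM. Car3, abundant in adipocytes, was at 2207 and 294 CPM. Of 68 measured markers in 6 lists of other cell types, 58 reached 10 CPM in both libraries. Lyz2, a macrophage lysozyme, was at 1177 and 2477 CPM. Xist, the noncoding RNA of X inactivation in female cells, was at 160 and 268 CPM.

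**Figure D1:**
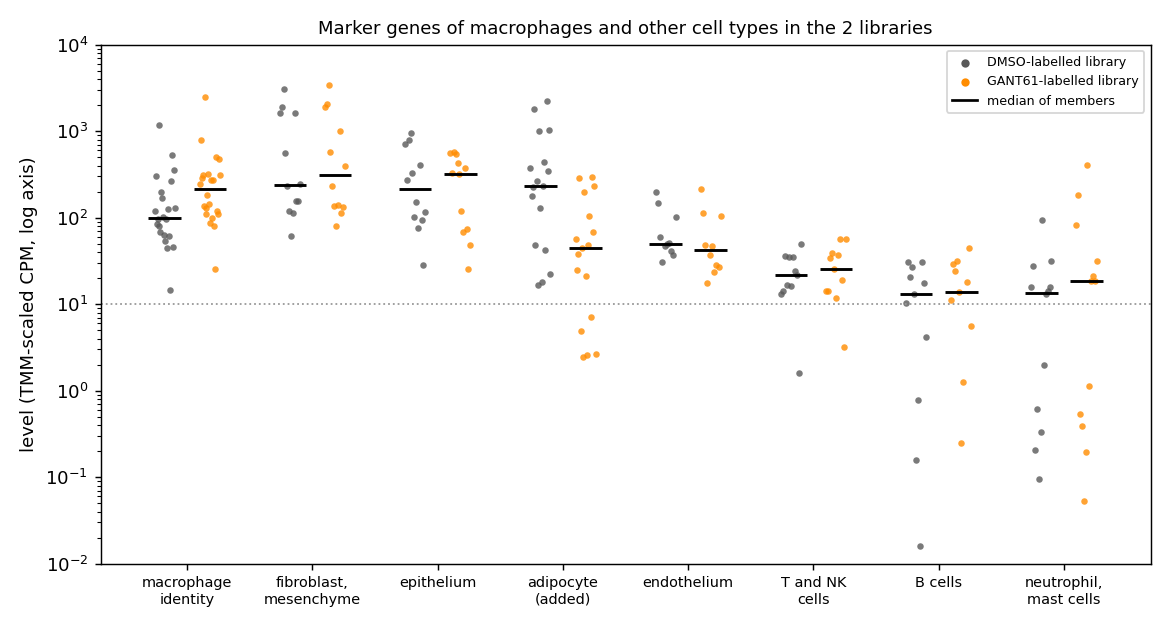
Levels of marker genes (TMM-scaled CPM, log axis) in the DMSO-labelled (grey) and GANT61-labelled (orange) library, where each point is a gene, black bars are medians and the dotted line marks 10 CPM, with genes at 0 reads in a library not drawn for it. The adipocyte median is 230 CPM in the DMSO-labelled and 45.2 CPM in the GANT61-labelled library, the macrophage median is 99.4 and 215 CPM, and the fibroblast median is 238 and 313 CPM.

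Between the libraries, 1972 genes were higher and 1436 lower in the GANT61-labelled library by the rule of size, among 13939 genes with a mean of at least 1 CPM. This is 24.4% of the genes considered. In simulated libraries, 16.61% of the unchanged genes were called at a coefficient of variation of 0.2 between replicates and 34.9% at 0.3. The number called is therefore within what replicate spread alone could give if it lay between these values, and that spread could not be measured. With a fold threshold of 2 the numbers were 972 and 595. Of the 44 fixed gene lists with a percentile, 19 stood above the random lists, 9 below and 16 within. Random members were drawn independently, while members of a fixed list can vary together and some lists share members. These numbers are therefore not counts of separate results.

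**Figure D2:**
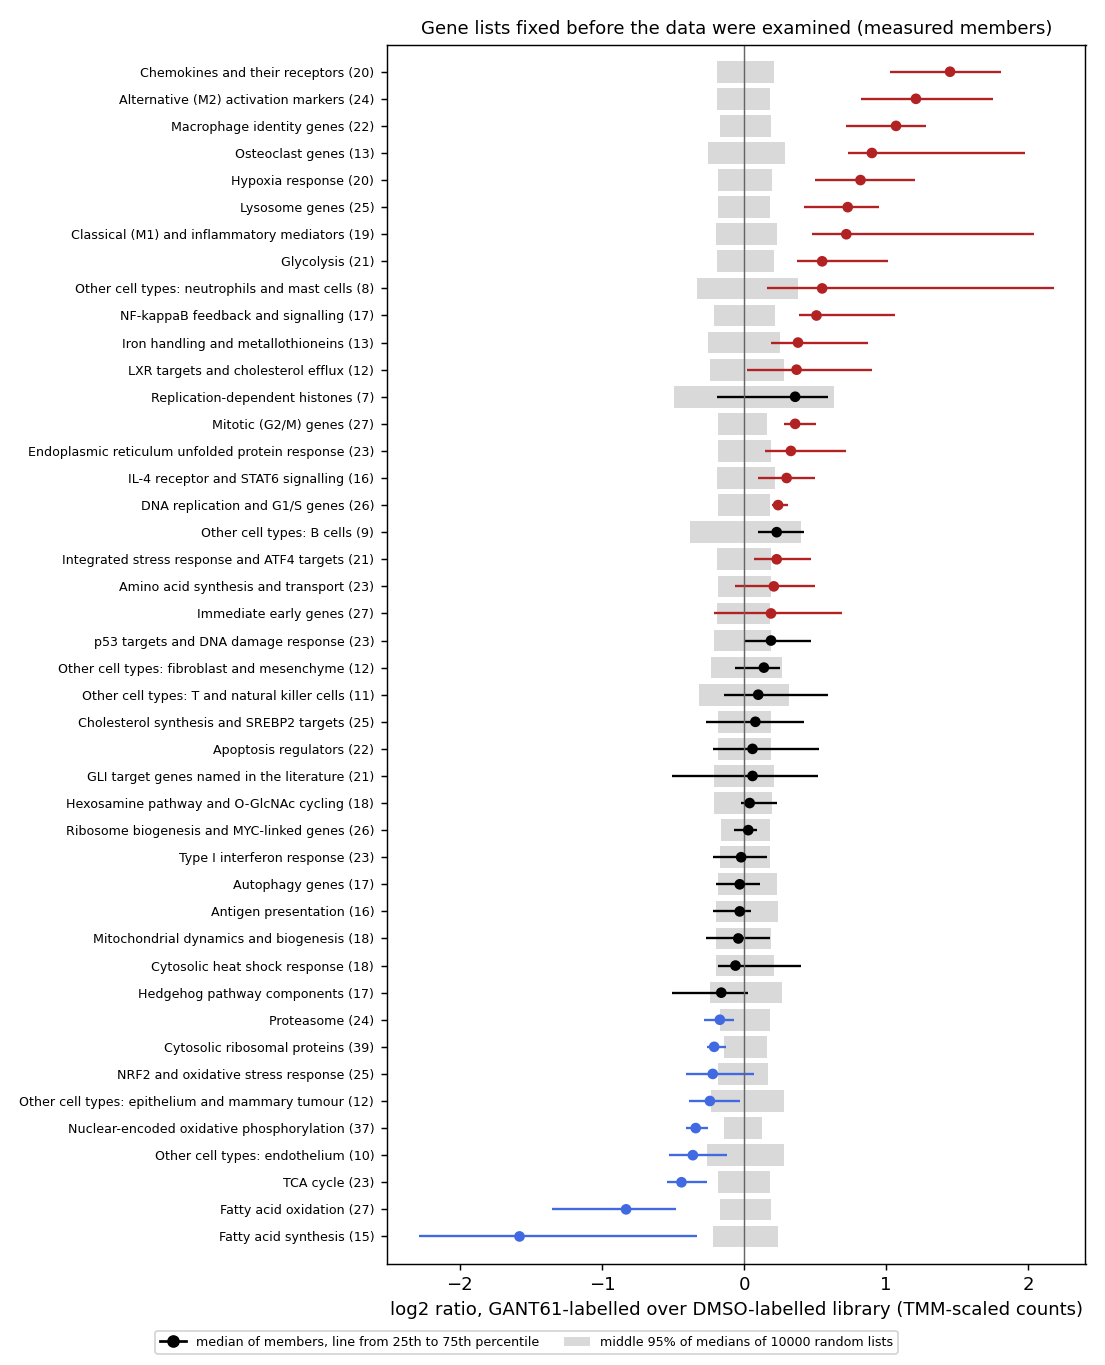
Median log2 ratio of each fixed gene list (points, red above and blue below the random range, black within), with the 25th to 75th percentile of members (lines) and the middle 95% of medians of 10000 matched random lists (grey bars). Chemokines have the highest median, 1.45, and fatty acid synthesis the lowest, -1.58.

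Among the Hedgehog readouts, Hhip was lower in the GANT61-labelled library and Ptch1 differed little. Ptch1, the Hedgehog receptor and a common GLI target, was at 22.6 CPM in the DMSO-labelled and 23.0 CPM in the GANT61-labelled library, a ratio of 1.02 (0.945 to 1.1). Hhip, a Hedgehog-binding inhibitor, had a ratio of 0.640 (0.588 to 0.696). Gli1, the GLI family member most often used as a readout, had 32 reads in the DMSO-labelled library and 7 in the GANT61-labelled library. Its ratio was 0.253 (0.0897 to 0.556), with a mean level below the floor of 1 CPM. Gli2 had a ratio of 1.1 (0.870 to 1.39), Gli3 of 0.705 (0.650 to 0.763), Smo of 0.715 (0.688 to 0.743) and Sufu of 0.929 (0.871 to 0.990). None of these 4 met the rule. Gli1 lies on chromosome 10 at 127329882 to 127341974, minus strand, and Ptch1 on chromosome 13 at 63508328 to 63573598, minus strand (both mm10).

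Over 17 measured Hedgehog components, 0 were higher, 4 were lower and 13 were neither. The lower members included Hhip and the co-receptors Boc, at a ratio of 0.382 (0.357 to 0.409), and Cdon, at 0.403 (0.377 to 0.429). Beside them, adipocyte markers, in a list written after the data were seen, had a median of -2.62 and fibroblast markers of 0.14. Which cells expressed the Hedgehog components was not tested. The median of the Hedgehog component list, -0.16, lay within the random range of -0.24 to 0.27. Its mean, -0.36, stood below the range of the means of random lists. Of 21 GLI target genes named in the literature, 3 were higher and 4 lower, with a median of 0.06. Spp1, the secreted protein osteopontin, had a ratio of 2.89 (2.86 to 2.92), Vegfa of 1.84 (1.79 to 1.90) and Bcl2, an apoptosis inhibitor, of 0.480 (0.458 to 0.503).

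Markers of alternative activation were higher as a group in the GANT61-labelled library, as were the general macrophage genes. Of 24 alternative activation markers, 19 were higher, 1 lower and 4 neither, with a median of 1.21 against a random range of -0.19 to 0.18. Cd163, a scavenger receptor, was at 151 and 1359.5 CPM, a ratio of 9.02 (8.83 to 9.22). Mrc1, the mannose receptor CD206, had a ratio of 5.54 (5.46 to 5.62). Pdcd1lg2 had a ratio of 4.95 (4.66 to 5.26) and Il1rn, the interleukin 1 receptor antagonist, of 4.72 (4.5 to 4.96). Arg1, which converts arginine to ornithine, had a ratio of 3.86 (3.81 to 3.91). Chil3 had a ratio of 3.81 (3.65 to 3.97), which is uncertain because close family members share its sequence. Retnla was at 385.5 and 391.6 CPM, a ratio of 1.02 (0.997 to 1.03).

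General macrophage genes, used here as identity markers, gave 17 higher, 2 lower and 3 neither of 22, with a median of 1.07. Cd68 had a ratio of 3.36 (3.26 to 3.47) and Itgam of 3.21 (3.12 to 3.31). Cd36, a fatty acid transporter also abundant in adipocytes, was lower at 0.226 (0.220 to 0.232). In the IL-4 receptor and STAT6 list, 3 of 16 were higher and 0 lower, with a median of 0.30. Il4ra, the IL-4 receptor alpha chain, had a ratio of 3.77 (3.68 to 3.86), Socs3 of 2.41 (2.33 to 2.49) and Il2rg of 2.0 (1.93 to 2.08). Stat6, the transcription factor downstream of IL-4, had a ratio of 1.25 (1.21 to 1.29), below the threshold. Ptprc, the pan-leukocyte marker CD45, had a ratio of 1.80 (1.76 to 1.84).

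Inflammatory genes were also higher in the GANT61-labelled library, beside the macrophage identity median of 1.07. Of 19 mediators of classical activation, 13 were higher, 0 lower and 6 neither, with a median of 0.72. Il1a had a ratio of 9.32 (8.76 to 9.94), Il1b of 5.86 (5.61 to 6.12) and Nos2, the inducible nitric oxide synthase, of 5.30 (5.07 to 5.54). Il6 had 91 and 374 reads, a ratio of 4.51 (3.59 to 5.76). Of 20 chemokines and their receptors, 17 were higher and 2 lower, with a median of 1.45. Cxcl3 had a ratio of 9.12 (7.32 to 11.6), Cxcl2 of 6.03 (5.50 to 6.64) and Ccl3 of 5.15 (4.55 to 5.86). Ccl12, whose sequence is close to that of other CC chemokines, had a ratio of 4.07 (3.84 to 4.32). The NF-kappaB feedback list had 7 of 17 higher and 0 lower, with a median of 0.51. Zc3h12a, an endonuclease that limits cytokine mRNA, had a ratio of 3.21 (2.94 to 3.51), and Nfkbiz of 3.18 (2.98 to 3.41).

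Interferon response genes stayed within the random range, with 2 higher, 1 lower and a median of -0.02 over 23 genes. Rsad2 had a ratio of 3.36 (3.17 to 3.57), Oas2 of 1.66 (1.56 to 1.77) and Rtp4 of 0.607 (0.586 to 0.628). Antigen presentation had 0 of 16 members called and a median of -0.03. Immediate early genes gave 9 higher and 1 lower of 27, with a median of 0.19 that no longer stood apart, at 0.14, with the GC trend removed. Dusp5 had a ratio of 3.02 (2.64 to 3.47), Fosl1 of 2.5 (2.15 to 2.93) and Ier3 of 2.44 (2.32 to 2.56). The lower member was Fos, at 0.636 (0.615 to 0.657). The neutrophil and mast cell list, one of the other cell types, had 3 higher and 1 lower of 8, with a median of 0.55. S100a9 had a ratio of 6.62 (6.29 to 6.97), S100a8 of 5.23 (4.89 to 5.62) and Ltf of 4.33 (4.21 to 4.46). Ngp, the lower member, had 123 and 65 reads, a ratio of 0.584 (0.424 to 0.792), and 4 members were neither.

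Lysosome and osteoclast genes were higher. Of 25 lysosome genes, 16 were higher and 0 lower, with a median of 0.73, and of 13 osteoclast genes 11 were higher and 0 lower, with a median of 0.90. Ctsk, the collagen-degrading protease cathepsin K, had a ratio of 3.91 (3.80 to 4.02) and Atp6v0d2, a proton pump subunit, of 4.68 (4.32 to 5.07). Ocstamp had 50 and 364 reads, a ratio of 7.94 (5.95 to 11). The iron and metallothionein list had 5 of 13 higher and 0 lower, with a median of 0.38, led by Hmox1, heme oxygenase 1, at 3.35 (3.23 to 3.47). Of 12 LXR targets, 5 were higher and 1 lower, with a median of 0.37. The cholesterol exporters Abca1 and Abcg1 had ratios of 3.13 (3.06 to 3.20) and 2.37 (2.27 to 2.47). Macrophage identity genes had a median of 1.07 beside these groups.

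**Figure D3:**
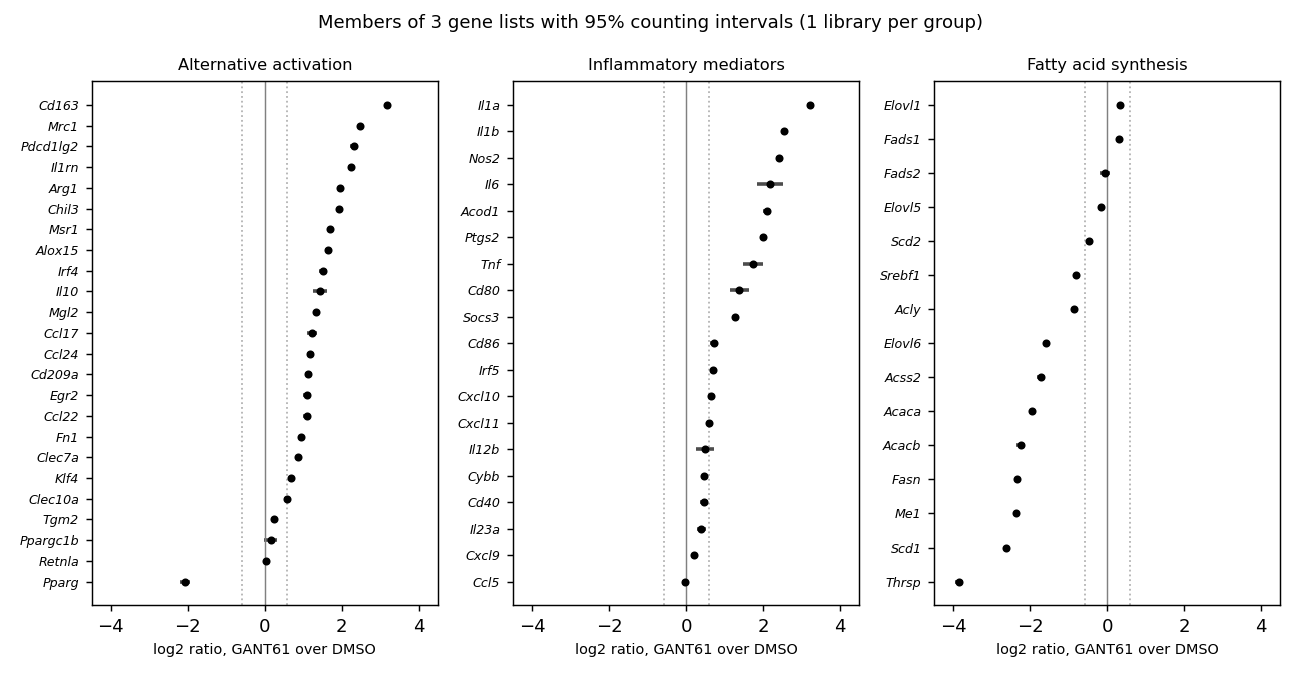
Log2 ratio of the GANT61-labelled over the DMSO-labelled library for members of 3 fixed lists with a mean of at least 1 CPM, where points are genes, bars are 95% counting intervals and dotted lines mark a ratio of 1.5 and its inverse. Cd163 and Il1a lie farthest to the right at ratios of 9.02 and 9.32, and Thrsp farthest to the left at 0.0688.

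Fatty acid synthesis and oxidation genes were lower in the GANT61-labelled library. Of 15 synthesis genes, 0 were higher and 10 lower, with a median of -1.58 against a random range of -0.22 to 0.24. Scd1, which desaturates fatty acids, was at 4867 and 783 CPM, a ratio of 0.161 (0.159 to 0.163). Fasn, the fatty acid synthase, had a ratio of 0.198 (0.195 to 0.2004) and Thrsp, a lipogenic regulator, of 0.0688 (0.0642 to 0.0737). Of 27 oxidation genes, 0 were higher and 17 lower, with a median of -0.83. Lpl, lipoprotein lipase, had a ratio of 0.222 (0.217 to 0.226), and Ppara had 318 and 34 reads, a ratio of 0.119 (0.0801 to 0.168). Cpt1b had a ratio of 0.130 (0.0949 to 0.173). Adipocyte markers were lower beside them, with 17 of 17 lower and a median of -2.62 in a list written after the data were seen. Of these 17 markers, 1 (Lpl) is also in the oxidation list. Fabp4 had a ratio of 0.159 (0.156 to 0.161) and Adipoq, the hormone adiponectin, of 0.151 (0.145 to 0.157).

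The glycolysis and hypoxia response lists stood above the random lists, and the medians of the TCA cycle and respiratory chain lists stood below them. Of 21 glycolysis genes, 10 were higher and 0 lower, with a median of 0.55. Slc2a1, the glucose transporter GLUT1, had a ratio of 3.63 (3.52 to 3.74), Slc16a3, a lactate exporter, of 3.49 (3.31 to 3.69) and Eno2 of 4.33 (3.85 to 4.90). Hypoxia response genes had 13 of 20 higher and 0 lower, with a median of 0.82. Hilpda had a ratio of 4.03 (3.76 to 4.32) and Adm of 2.66 (2.44 to 2.90). Beside these higher lists, macrophage identity genes had 17 of 22 higher and a median of 1.07. The TCA cycle list had 5 of 23 lower and 0 higher, with a median of -0.44. Pcx, pyruvate carboxylase, also abundant in adipocytes, had a ratio of 0.178 (0.170 to 0.187) and Pdha1 of 0.553 (0.539 to 0.568). Nuclear-encoded respiratory chain genes had a median of -0.34 with 0 of 37 called, and Atp5b had a ratio of 0.789 (0.780 to 0.797). The adipocyte marker median of -2.62 stands beside these lower lists too. The list of hexosamine pathway and O-GlcNAc cycling genes had 3 of 18 higher, 0 lower and a median of 0.04 within the random range. Of all genes considered, 14.1% were higher. The hexosamine pathway makes the sugar donor for O-GlcNAc, though not every list member acts in that direction. The higher members of the list were Gnpda1 at 2.02 (1.92 to 2.13), Amdhd2 at 1.70 (1.58 to 1.83) and Gfpt2 at 1.68 (1.55 to 1.82). Ogt and Gfpt1, which add O-GlcNAc and start the pathway, had ratios of 1.23 (1.20 to 1.27) and 1.20 (1.16 to 1.24), below the threshold.

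Endoplasmic reticulum and integrated stress response genes stood above the random lists, as macrophage identity genes did at a median of 1.07. The list of NRF2 and oxidative stress response genes stood below the random lists. The endoplasmic reticulum list had 9 of 23 higher and 0 lower, with a median of 0.33, led by Ero1l, a hypoxia-responsive oxidase, at 4.14 (4.01 to 4.27). The integrated stress response had 5 of 21 higher and 0 lower, with a median of 0.23, and Ddit3, the factor CHOP, had a ratio of 2.37 (2.20 to 2.57). Amino acid synthesis and transport had 3 higher and 2 lower of 23, with a median of 0.21, while its mean, 0.17, did not stand apart. Mthfd2 had a ratio of 2.26 (2.10 to 2.43) and Slc1a5, a glutamine transporter, of 0.368 (0.356 to 0.380). The NRF2 list had 1 higher and 5 lower of 25, with a median of -0.22. Its lower members included Me1 at 0.193 (0.185 to 0.202) and Cat, catalase, at 0.455 (0.442 to 0.470), and its higher member was Hmox1. Of its members, 5 are also in other lists, among them Me1 in fatty acid synthesis, and adipocyte markers had a median of -2.62 beside this list. The p53 list had 6 higher and 2 lower of 23, with a median of 0.19 just inside the random range. It stood apart with DESeq2 size factors, at 0.18. Cdkn1a had a ratio of 2.60 (2.46 to 2.74) and Phlda3 of 0.416 (0.393 to 0.440). Heat shock genes had 3 higher and 1 lower of 18, with a median of -0.06, and Hspa1a, near-identical to Hspa1b, had a ratio of 2.38 (2.13 to 2.65).

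Cell cycle lists stood above the random lists, beside the macrophage identity median of 1.07, and ribosomal protein and proteasome lists below them. DNA replication genes had 2 of 26 higher and 0 lower, with a median of 0.24, and mitotic genes 5 of 27 higher and 0 lower, with a median of 0.36. Rrm2 had a ratio of 1.77 (1.67 to 1.87) and Mki67, a proliferation marker, of 1.61 (1.57 to 1.65). Cytosolic ribosomal proteins had 0 of 39 called and a median of -0.21, and proteasome genes 0 of 24 and a median of -0.17. With the trend in gene length removed these medians were -0.09 and -0.06 and no longer stood apart. Apoptosis regulators had 5 higher and 3 lower of 22, with a median of 0.06, and Bmf had a ratio of 0.448 (0.422 to 0.475). Cholesterol synthesis had 2 higher and 2 lower of 25 and a median of 0.08, with Insig1 at 0.532 (0.509 to 0.556). Replication-dependent histones had 2 higher and 1 lower of 7 and a median of 0.36 within the random range. Their reads are shared between near-identical genes, so the values are uncertain.

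Markers of other cell types differed by type. Fibroblast markers had 1 higher and 1 lower of 12, with a median of 0.14, and Postn, a matrix protein, had a ratio of 0.613 (0.606 to 0.619). Endothelial markers had 2 of 10 lower, with a median of -0.36, and Cldn5 had a ratio of 0.471 (0.441 to 0.502). Epithelial markers had 1 higher and 2 lower of 12 and a median of -0.24, which no longer stood apart, at -0.17, with the length trend removed. Krt5, a basal keratin, had a ratio of 3.13 (3.04 to 3.22), and Csn2, a milk casein, of 0.412 (0.394 to 0.431). T and natural killer cell markers had 3 of 11 higher and a median of 0.10, with Cd4, also found on macrophages, at 2.36 (2.19 to 2.54). B cell markers had 2 higher and 1 lower of 9 and a median of 0.23, with Cd22 at 2.52 (2.35 to 2.71). Autophagy, with a median of -0.03, mitochondrial dynamics, at -0.04, and ribosome biogenesis, at 0.03, lay within the random range with fewer than 3 called members each.

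By the naming rule, the largest ratio was that of Gsdmc2 and the smallest that of Csn1s2a. Gsdmc2, a gasdermin, had 3 and 697 reads, a ratio of 218 (87.2 to 1244), and lies on chromosome 15 at 63824346 to 63845177, minus strand, beside close family copies that make its value uncertain. Clca1, a secreted goblet cell protein on chromosome 3 at 145003817 to 145032776, minus strand, had a ratio of 32.4 (27.6 to 38.4). Msx3 had a ratio of 28.8 (21.9 to 39.5), Slc34a2, a phosphate transporter, of 18.9 (14.9 to 24.6), and Mill1 of 17.4 (12.9 to 24.8). Ogdhl, Fcrlb, Prl2c3, Cma2 and the chemokine Cxcl5 had ratios from 16.8 to 11.5, of which Prl2c3 is uncertain because of near-identical copies. Csn1s2a, a milk casein on chromosome 5 at 87774567 to 87788797, plus strand, had 3704 and 3 reads, a ratio of 0.00103 (0.000184 to 0.00261). The casein Csn1s1 had a ratio of 0.0105 (0.00718 to 0.0144), Glycam1 of 0.0401 (0.0308 to 0.0507) and Tph1, which starts serotonin synthesis, of 0.0524 (0.0439 to 0.0618). Ibsp, Thrsp, Trpm3, Nnat, Arxes1 and Pnpla3, a lipid hydrolase, had ratios from 0.0593 to 0.0795.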

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

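The length, GC and marker removal settings were chosen after the data were seen; the others were planned. The numbers of genes higher and lower moved by over 1.5 times only with the fold threshold, to 972 and 595 at 2 and to 400 and 247 at 3, because a stricter threshold keeps fewer genes. The share of called genes that were higher was 57.9%, and from 52.9% with total counts to 62% at a threshold of 2. Requiring no counting interval changed no count, so at this depth the interval does not limit the calls. No direction of a called value turned. Lists outside the random range numbered 28 of 44, and from 25 with the length trend removed to 29. A further check of the respiratory chain, TCA cycle, ribosomal protein and proteasome medians against length and GC trends was written before its result was seen and then left out of the weighed patterns, after the result was seen, to keep these to 3. With the length trend removed the medians were -0.27, -0.36, -0.09 and -0.06, and with the GC trend removed -0.34, -0.42, -0.21 and -0.13. Without the GC trend only the proteasome list ceased to stand apart, and without the length trend the ribosomal protein and proteasome lists did. Neither trend thus accounted for the respiratory chain and TCA cycle medians, and length was left undecided for the other lists. With no mitochondrially encoded genes analysed, the setting that left these out reduced to the 10 most abundant genes. No paired analysis was possible because each group had 1 library, so no library could be left out either.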

Other observations

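The scalings of the libraries were planned, and all other tests in this part, with the bounds set for the scalings, were chosen after the results were seen. Matrix metalloproteinases and keratins of stratified and wound epithelium were higher in the GANT61-labelled library, in lists written after the data were seen. Of 15 measured metalloproteinases, 8 were higher, 1 lower and 6 neither, with a median log2 ratio of 1.11. Beside it, macrophage identity genes had a median of 1.07 and the neutrophil and mast cell list of 0.55. Mmp12, the macrophage elastase, was at 148 and 1001.7 CPM, a ratio of 6.75 (6.61 to 6.90). Mmp13 had a ratio of 6.53 (6.36 to 6.70), Mmp10 of 6.92 (6.40 to 7.49) and Mmp8, a neutrophil collagenase, of 9.95 (8.35 to 12). Mmp14 had a ratio of 1.02 (1.0 to 1.03), and Mmp28 was lower at 0.427 (0.35 to 0.516).

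Of 12 keratins and cornified envelope genes, 11 were higher and 0 lower, with a median of 1.70. Krt6a, induced in wounded skin, had a ratio of 7.31 (6.48 to 8.29) and Krt16 of 3.94 (3.42 to 4.56), while Krt14 had 1.32 (1.3 to 1.35). Krt6a and Krt6b share much of their sequence, so their split is uncertain. The milk protein list had 6 of 6 measured members lower, with a median of -3.34, and the erythroid list 1 of 7 lower, with a median of -0.53. Hba-a1, a haemoglobin chain, was at 233 and 166 CPM.

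Markers of fibroblasts and epithelium were abundant in both libraries, and those of endothelium and lymphocytes were detected at lower levels, although the cells were labelled as a macrophage line that was established from a male mouse, and Xist was at 160 and 268 CPM. A trace of foreign RNA is argued against by 4 fibroblast markers, Col1a1, Col1a2, Col3a1 and Postn, among the 100 most abundant genes of both libraries. RNA of the labelled line alone is argued against as well, by these markers and by Xist in a line from a male mouse. RNA of a mixed tissue stays open, since the 85.3% of the 68 markers that reached 10 CPM in both libraries are the pattern itself and do not test it. Columns that belong to other samples stay open too: 0 of the 2 column numbers matched the title number of their sample, and numbers alone cannot decide it. No biological explanation was tested. Transcripts of milk caseins were among those present. Csn2 was at 117 CPM in the DMSO-labelled and 48.1 CPM in the GANT61-labelled library, and Csn1s1 at 59.7 and 0.616 CPM. They make mammary tissue a candidate, but which tissue it would be was not tested.

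Adipocyte, milk protein and fatty acid synthesis genes were lower in the GANT61-labelled library. The choice among the 4 scalings does not account for the lower values, since the fatty acid synthesis median was no higher than -1.58 under each. Their factors for the GANT61-labelled over the DMSO-labelled library ran only from 0.97 to 1. They could not have moved the median far. A smaller share of epithelium as a whole is argued against for the milk proteins. The other epithelial markers had a median of -0.15 (-0.37 to 0.25, from resampling members). They mix the basal keratin Krt5, at a ratio of 3.13, with Krt18 of simple epithelium, at 0.583. A smaller share of milk-producing cells alone was therefore not tested. A smaller share of adipocytes stays open for the synthesis genes. Adipocyte markers that are not synthesis enzymes had a median of -2.62 (-2.80 to -2.36). The synthesis median lay 1.04 (0.32 to 2.3) above it, with both intervals again from resampling members. The adipocyte list was written after the data were seen, so its low median does not test this explanation. An effect of GANT61 on lipid synthesis within a cell type stays open and untested.

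Macrophage, alternative activation and inflammatory genes were higher together in the GANT61-labelled library. The choice among the 4 scalings does not account for the higher values, since the macrophage identity median was at least 1.03 under each. These scalings differed too little to move it far. A larger share of macrophages stays open. Alternative activation exceeded macrophage identity by 0.14 (-0.15 to 0.67) and the inflammatory list differed from it by -0.35 (-0.61 to 0.97). These intervals, from resampling members, give the spread among the chosen genes, not the uncertainty of a cell share. They are also wide, so they cannot decide it. The 25th to 75th percentiles of members were 0.82 to 1.75 for alternative activation and 0.48 to 2.04 for the inflammatory list. For macrophage identity they were 0.72 to 1.28, so 1 common factor does not describe the single genes. A larger share of all leukocytes cannot be told apart from a larger share of macrophages. The higher of the T and B cell medians was 0.23, and the T cell median reached 0.99 in resampling of its members. An effect of GANT61 on activation within macrophages stays open and untested with 1 library per label.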
